A study of Homo sapiens with 6 samples.

How the data were processed

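Total RNA of HCT-15 cells was extracted with Trizol and labelled with biotin for Affymetrix arrays, per the labels' protocols. The authors deposited 1 table of log2 values, with 1 column for each of the 6 arrays and 1 row for each of 1259 probe sets. RMA, which corrects background, normalizes between arrays and summarises the probes of a set, is named per the submitters' processing notes. Its version and settings, the array platform and a genome build are not given in the sources used here. That the deposited values are log2 was taken from their range, 2.13 to 13.67, and their like medians. The number of columns of values left unused was 0. The scanner files and any detection calls were not used here, so a low probe set value cannot be set against its background. RMA compresses differences between dim probe sets, and quantile steps force arrays toward one distribution, so a change shared by most genes would be reduced.

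Samples were grouped by source name and treatment entry, 3 untreated and 3 treated. The title of untreated replicate 3 names it as treated, against both of those labels and the opening letter of the title itself. All 6 titles hold the word control, so it separates no arrays. The counts of called probe sets, the named genes and the camera tests of lists were also computed without this array. No pair of arrays held the same values: at most 5 of the 1259 values were identical between any pair.

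Probe set names contain RefSeq transcript identifiers. These were matched without versions to a RefSeq gene table (assembly GRCh38.p14), used for names only. The match gave 1 symbol for 1043 probe sets and 927 genes, and 216 probe sets stayed unnamed, 26 with an identifier that did not match and 190 with none. All 1259 entered the test, since 0 were controls. For the 93 genes with several probe sets, the one with the highest mean over the 6 arrays stood for the gene. Of the named genes, the other probe sets of DLL3, FUT3, MUC1 and NEU1 had the same direction and call. Endings of probe set names mark several sets as able to bind transcripts of more than one gene, among them those of FUT6, NEU1, ST3GAL6, GCNT1, VCAN, GALNT6, FUT2, CHST11, DLL3, MAN1B1, MAN2A2 and BGN, whose values are less certain for that reason. Coordinates are not given, as no build is named for the array.

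Tests were run in R 4.3.3 with limma 3.58.1. A linear model with 1 term for treatment was fitted to the log2 values of all 6 arrays (lmFit), followed by eBayes with its default prior, two-sided p-values and Benjamini-Hochberg adjustment over the 1259 probe sets. A probe set with an adjusted p under 0.05 was called, and calls were also counted at 1.5-fold and 2-fold. No filter on dim probe sets was applied. Errors beside log2 changes are standard errors of limma's fit, with 3 arrays per group. Folds are the log2 changes taken out of the log scale.

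Fixed before the data were examined were 25 gene lists, covering glycan assembly pathways, glycan carriers and binding proteins, signalling families on such arrays, and markers of leukocytes and of stromal and endothelial cells. Several genes, among them MUC1, CD22 and CD33 and some transferases, stand in more than 1 list. For 3 listed genes the current symbol was used. Lists were compared with the other genes in limma's camera test (two-sided, preset correlation 0.01, Benjamini-Hochberg over the 25 lists), with an estimated correlation and the fry test as alternatives. Each list's calls were also adjusted over the list alone.

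The genes named were set by a rule fixed at the same time: all measured genes of sialyl Lewis x assembly and MUC1, the 12 largest rises and 8 largest falls among called genes whose groups did not overlap, and the 2 called genes with the smallest p in each list. This gave 67 genes. Others are named where a count was 5 or fewer, or to describe families in the closing section, and were chosen after their values were seen.

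The steps were tested on simulated data: 200 of 1259 probe sets were changed in simulated arrays of treated against untreated cells. Of 100 changed by 0.585 on the log2 scale 100% were called, and of 100 changed by 1 likewise 100%. False calls numbered 6 (2.91% of calls), and there were 0 calls where nothing was changed. A list that was shifted was the only one called, with all its members moved by the same amount and no other gene changed. The simulated noise was independent and normal, with the spread that limma had fitted. These shares therefore check that the steps work, and do not measure sensitivity in the real arrays. Nor does the shifted list show that the test would find a list whose members move both ways.

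Alternatives were quantile normalization, centring each array on its median, leaving out the dimmest probe sets (840 stayed, with a mean level of at least 4.9), an intensity trend in eBayes, array weights, the replicate number as a block, each array left out in turn, an ordinary equal-variance test, looser and stricter thresholds, and, for lists, the mean of a gene's probe sets. Their effects are given in the closing section.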

Results

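Gene expression was compared in HCT-15, an established human colon cancer cell line, with and without 5-aza-2'-deoxycytidine, a cytosine analogue that is built into DNA and blocks the upkeep of DNA methylation. The series holds 6 arrays of total RNA, 3 from untreated and 3 from treated cells, and each gave a log2 value for 1259 probe sets. Of these, 1043 were matched to 1 gene symbol each and cover 927 genes, many of them glycosyltransferases, glycan-binding proteins, proteoglycans and growth factors. Array medians lay between 5.81 and 5.92. Pairs of untreated arrays correlated at 0.9978 to 0.9982 and pairs of treated arrays at 0.9974 to 0.9987, while pairs across the groups lay at 0.9817 to 0.9844. The median absolute log2 difference was 0.076 to 0.117 within a group and 0.172 to 0.209 between groups. The dose and duration of treatment are not given in the sources used here. Nothing in the labels says that replicates came from separate cultures, so p-values measure the spread between these samples, which may be technical. The number of arrays limits the precision. The title of untreated replicate 3 calls it treated, while its source name, its treatment entry and the letter that opens its title, shared with the other untreated arrays, mark it as untreated, and it was grouped so. The word control stands in the titles of all 6 arrays, treated ones included, and was not used for grouping.

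The submitters asked how glycan-related genes change in cells that display more sialyl Lewis x, a selectin ligand, after the drug. Treatment was followed by large changes in single genes of glycosaminoglycan metabolism, signalling and lectins. BMP7, a bone morphogenetic protein, was 9.98-fold higher in treated cells, CHST15, a chondroitin sulfate sulfotransferase, 9.66-fold, and VCAN, the chondroitin sulfate proteoglycan versican, 9.52-fold. SULT1C2, a cytosolic sulfotransferase, and TGFB3, a transforming growth factor, were each 3.63-fold lower. The mucin gene MUC1 was 2.47-fold higher, whereas the genes of sialyl Lewis x assembly went in both directions.

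In limma's test with Benjamini-Hochberg adjustment, 438 of the 1259 probe sets (34.8%) passed an adjusted p under 0.05, of which 227 rose and 211 fell. At 1.5-fold or more there were 169, with 100 rises and 69 falls, and at 2-fold or more 58, with 42 rises and 16 falls. By gene, 183 rose and 163 fell. In 581 probe sets (46.1%) the 3 treated values did not overlap the 3 untreated values, against 10% by chance. After each array was centred on its median the split was 197 rises and 311 falls, and after quantile normalization it was 220 rises and 265 falls. Without untreated replicate 3, whose title conflicts with its other labels, 440 probe sets passed, 225 up and 215 down.

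**Figure D1:**
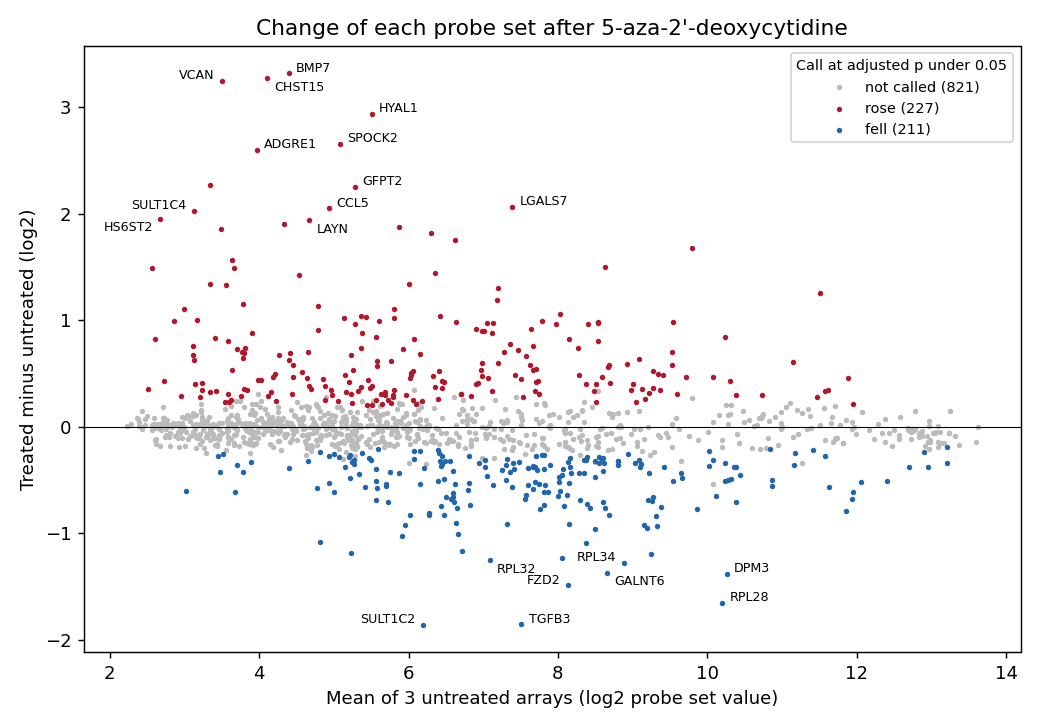
Each point is 1 probe set, with its mean over the 3 untreated arrays (log2) on the horizontal axis and the treated minus untreated difference (log2) on the vertical axis. Red points rose (227), blue points fell (211) and grey points were not called (821) at an adjusted p under 0.05, and the 12 rises and 8 falls named by the fixed rule are labelled, from 3.32 for BMP7 to -1.86 for SULT1C2.

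Among the 12 largest rises, BMP7 went from 4.40 to 7.72 (log2 change 3.32 ± 0.15 SE, adjusted p = 5.61e-08) and CHST15 from 4.11 to 7.38 (3.27 ± 0.09, adjusted p = 2.77e-09). VCAN rose by 3.25 ± 0.18 (adjusted p = 2.94e-07) and HYAL1, a hyaluronidase, by 2.94 ± 0.09 (7.66-fold, adjusted p = 8.26e-09). SPOCK2, a proteoglycan of the testican family, was 6.3-fold higher, and ADGRE1, an adhesion G protein-coupled receptor, 6.06-fold higher. GFPT2, an isoform of the first enzyme of the hexosamine pathway, was 4.78-fold higher. LGALS7, a galectin, was 4.19-fold higher with the widest error of the 12 (2.07 ± 0.28, adjusted p = 0.000186). The chemokine CCL5 rose 4.14-fold, SULT1C4 rose 4.07-fold, the heparan sulfate sulfotransferase HS6ST2 rose 3.88-fold and the hyaluronan receptor LAYN rose 3.84-fold. All 12 rose in every alternative, except that SULT1C4 and HS6ST2 lie below the level at which the dimmest probe sets were left out.

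The largest falls were those of SULT1C2 (6.19 to 4.33, log2 change -1.86 ± 0.10 SE, adjusted p = 2.42e-07) and TGFB3 (7.51 to 5.65, -1.86 ± 0.12, adjusted p = 6.94e-07). Probe sets of the ribosomal protein genes RPL28, RPL34 and RPL32 were 3.15-fold, 2.43-fold and 2.38-fold lower. FZD2, a Wnt receptor, was 2.81-fold lower. DPM3, a subunit of dolichol-phosphate mannose synthase, was 2.61-fold lower, and GALNT6, which starts mucin-type O-glycans, was 2.59-fold lower. These 8 genes fell in all 13 alternatives.

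The genes that build sialyl Lewis x, a sialylated and fucosylated glycan bound by E-selectin, did not move in one direction. Of 12 measured, 2 rose, 4 fell and 6 were not called, and adjusted over the list alone 3 rose and 6 fell. ST3GAL6, an α2,3-sialyltransferase, went from 2.73 to 3.17 (log2 change 0.43 ± 0.09 SE, 1.35-fold, adjusted p = 0.0025), and only 4.69% of probe sets had a mean level at or below its own. B4GALT1, a galactosyltransferase, rose from 9.27 to 9.64 (0.37 ± 0.10, 1.29-fold, adjusted p = 0.0128). ST3GAL3, another α2,3-sialyltransferase, was 1.7-fold lower (-0.76 ± 0.09, adjusted p = 8.41e-05). GCNT1, which forms the core 2 O-glycan branch, was 1.64-fold lower (-0.71 ± 0.11, adjusted p = 0.000361). The α1,3/4-fucosyltransferase FUT3 was 1.43-fold lower (-0.51 ± 0.11, adjusted p = 0.00485). B3GNT3, which extends core 1, was 1.3-fold lower (-0.37 ± 0.10, adjusted p = 0.0115). The fucosyltransferases FUT4 (8.01 to 7.85, adjusted p = 0.0913), FUT5 (6.14 to 6.13, 0.953), FUT6 (6.78 to 6.88, 0.34), FUT7 (5.44 to 5.28, 0.0923) and FUT9 (2.92 to 2.94, 0.922) were not called. ST3GAL4 went from 7.16 to 7.41 (adjusted p = 0.0584). FUT3, FUT5 and FUT6 are close paralogs, so their probe sets may share signal.

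As a list, these 12 genes did not differ from the other genes of the array in limma's camera test (adjusted p = 0.629 over the 25 lists, and adjusted p = 0.89 with an estimated correlation). The fry test gave an adjusted p = 0.0178 for a shift on balance downward and an adjusted p = 0.0011 for changes in either direction, and it does not compare the list with other genes. B4GALT1 missed the threshold without untreated replicate 2 (adjusted p = 0.0536), after quantile normalization (0.0629) and in an ordinary equal-variance test (0.104), its highest value over the alternatives, the lowest being 0.00355. ST3GAL4 passed it without untreated replicate 3 (0.0478), without treated replicate 3 (0.0172) and with array weights (0.00984), in a range up to 0.197. FUT7 passed it after quantile normalization (0.0202), after median centring (0.0239) and in the ordinary test (0.0264), in a range up to 0.242, and FUT4 after median centring (0.0273, up to 0.234). FUT3 (0.0856) and B3GNT3 (0.0985) missed it in the ordinary test, with lowest values of 0.00139 and 0.0073.

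**Figure D2:**
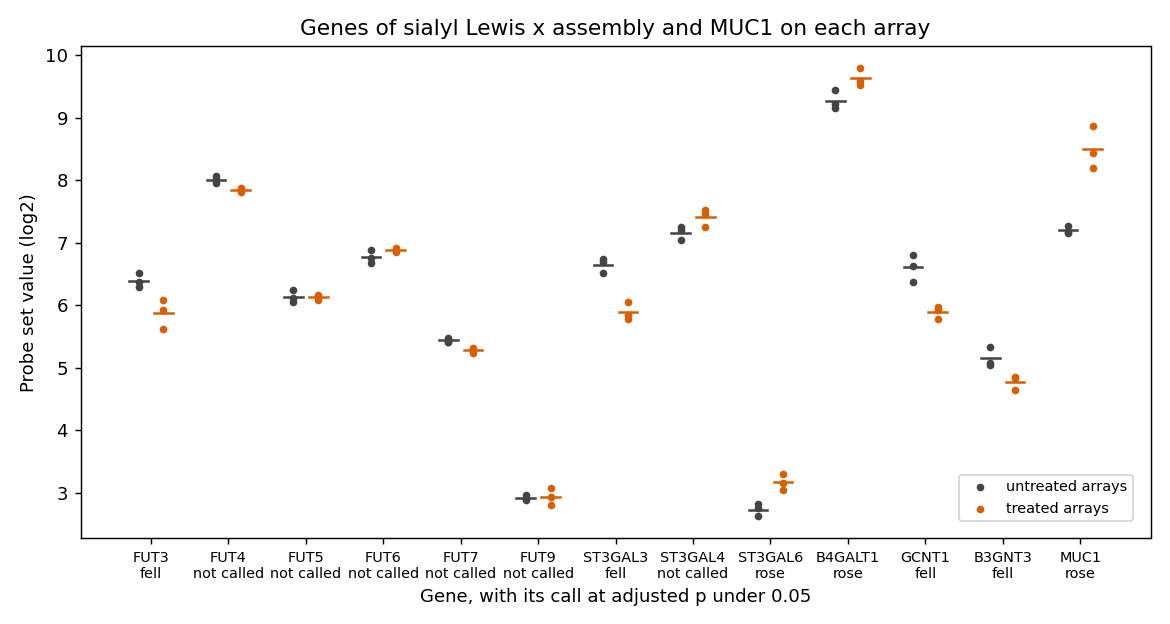
Probe set values (log2, vertical axis) of the 12 sialyl Lewis x genes and MUC1 are shown for the 3 untreated arrays (grey points) and the 3 treated arrays (orange points), with group means as short lines and the call under each gene. The MUC1 mean moved from 7.20 to 8.50, while ST3GAL6 rose from 2.73 to 3.17 at the low end of the scale.

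MUC1, a transmembrane mucin, rose by 1.30 ± 0.14 on the log2 scale (adjusted p = 3.3e-05), and its other 2 probe sets rose by 0.90 and 0.98. Of 11 measured mucin genes 3 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.526), and 2 fell after quantile normalization or median centring. MUC13 was 1.95-fold higher (adjusted p = 6.15e-06). Members given here and below with a log2 change but neither a fold nor an adjusted p lie outside the fixed rule for named genes and were chosen after their values were seen. They were MUC4 (0.615 ± 0.088) and MUC20 (-0.93 ± 0.12) among the mucins. Selectins and proteins that carry their ligands had 4 rises and 1 fall among 12 genes, also adjusted over the list alone (camera adjusted p = 0.526). Besides MUC1, the hyaluronan receptor CD44 was 1.55-fold higher (adjusted p = 0.000124), and the lysosomal membrane proteins LAMP1 (0.30) and LAMP2 (0.48) rose. The CD44 probe set started from a low level of 3.13, and only 11.9% of probe sets had a mean level at or below its own. Without the dimmest probe sets 3 rises and 1 fall were called. PODXL, podocalyxin, fell by 0.47. The ordinary test called 2 of the 4 rises.

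No fucosyltransferase gene rose. Of 13 measured, 0 rose and 5 fell in limma's test, also adjusted over the list alone (camera adjusted p = 0.526), with 0 rises at an unadjusted p under 0.05 and 0 in the ordinary test. FUT2, which makes the H antigen in secretions, was 1.88-fold lower (adjusted p = 4.69e-05), and POFUT3, listed under its older symbol FUT10, was 1.34-fold lower (adjusted p = 0.00302). FUT3 was among the 5, as were FUT1 (-0.36) and the core fucosyltransferase FUT8 (-0.29). Without untreated replicate 1, without untreated replicate 2 and in the ordinary test there were 3 falls, against 6 after quantile normalization and 7 after median centring.

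Of 20 sialyltransferase genes 7 rose and 2 fell, and adjusted over the list alone 10 rose and 2 fell (camera adjusted p = 0.526). ST6GALNAC2, which adds sialic acid to O-linked GalNAc, was 1.89-fold higher (adjusted p = 6.34e-06). ST6GAL1, the α2,6-sialyltransferase of N-glycans, was 1.62-fold higher (adjusted p = 8.39e-05). The 2 falls were ST3GAL3 and ST6GALNAC4 (-0.43 ± 0.07). With the dimmest probe sets left out, 2 rises and 2 falls were called.

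Polypeptide GalNAc transferases, which start mucin-type O-glycans, had 2 rises and 5 falls among 18 genes, also adjusted over the list alone (camera adjusted p = 0.526). GALNT6 fell by 1.37 ± 0.12 on the log2 scale (adjusted p = 7.99e-06) and GALNT12 was 1.95-fold lower (adjusted p = 5.95e-06). GALNT11 (-0.69), GALNT5 (-0.32) and GALNT1 (-0.30) also fell, and GALNT7 (0.59) and GALNT14 (0.42) rose, with 1 rise left without treated replicate 2 and in the ordinary test. Among 12 genes of O-glycan cores and their extension 4 rose and 2 fell, and adjusted over the list alone 5 rose and 3 fell (camera adjusted p = 0.82). There were 4 rises and 5 falls after quantile normalization and 4 and 4 after median centring, and 1 fall was left in the ordinary test. C1GALT1, the core 1 galactosyltransferase, was 1.63-fold higher (adjusted p = 0.000291), and GCNT3 (0.54) and ST3GAL1 (0.33) rose beside ST6GALNAC2. The 2 falls were GCNT1 and B3GNT3.

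For lactosamine chain extension 4 of 17 genes rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.982), against 2 and 3 after quantile normalization and 3 and 6 after median centring. B3GNT2, a polylactosamine synthase, was 1.87-fold higher (adjusted p = 1.96e-05) and B3GNT4 was 1.27-fold lower (adjusted p = 0.00323). B3GNT8 (0.30) and GCNT2 (0.25) rose and B4GALT2 (-0.32) fell, besides B4GALT1 and B3GNT3, and 2 rises were left without untreated replicate 2, and 2 rises and 1 fall in the ordinary test. In glycolipid synthesis 3 of 14 genes rose and 2 fell, and adjusted over the list alone 4 rose and 2 fell (camera adjusted p = 0.82). UGCG, which makes glucosylceramide, was 1.51-fold higher (adjusted p = 0.000672) and B3GALT4, a ganglioside galactosyltransferase, was 1.67-fold lower (adjusted p = 8.05e-05). ST8SIA1 (0.33) and A4GALT (0.28) rose and UGT8 (-0.50) fell.

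Among 14 genes of N-glycan branching and trimming 2 rose and 4 fell, and adjusted over the list alone 3 rose and 4 fell (camera adjusted p = 0.82). The mannosidase MAN1B1 was 1.34-fold lower (adjusted p = 0.00116) and MAN2A2 1.26-fold lower (adjusted p = 0.00487). MAN1A1 (-0.49) and FUT8 (-0.29) fell, and MAN2A1 (0.35) and MGAT5B (0.21) rose. No rise was left with the replicate number as a block (0 and 4) or in the ordinary test (0 and 2). Leaving out untreated replicate 1, untreated replicate 2, treated replicate 1 or treated replicate 3 left 1 rise, as did median centring and the intensity trend. The dolichol pathway and oligosaccharyltransferase, which build and transfer the N-glycan precursor, had 1 rise and 7 falls among 19 genes, and 1 and 8 adjusted over the list alone. The camera test gave an adjusted p = 0.374 (adjusted p = 0.89 with an estimated correlation). DPM3 fell by 1.38 ± 0.11 on the log2 scale (adjusted p = 3.5e-06) and ALG9, a mannosyltransferase, was 1.67-fold lower (adjusted p = 3.78e-05). ALG10 (0.34) was the rise, and there were 2 rises without treated replicate 3 and with array weights. The falls numbered 8 after quantile normalization and 10 after median centring.

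Nucleotide sugar synthesis had 6 rises and 11 falls among 24 genes, and 7 and 11 adjusted over the list alone (camera adjusted p = 0.526). GFPT2 rose by 2.26 ± 0.12 on the log2 scale (adjusted p = 1.94e-07), while MPI, mannose phosphate isomerase, was 1.7-fold lower (adjusted p = 7.51e-06). The ordinary test called 2 of the rises. Among 14 nucleotide sugar transporter genes 2 rose and 5 fell, and adjusted over the list alone 2 rose and 6 fell (camera adjusted p = 0.545). SLC35D3 was 1.63-fold higher (adjusted p = 0.000123) and SLC35A5 was 1.5-fold lower (adjusted p = 0.00057). SLC35C1, the GDP-fucose transporter, fell by 0.55, SLC35B2 (-0.48), SLC35B3 (-0.38) and SLC35B4 (-0.35) also fell, and SLC35D2 (0.23) rose. There were 3 falls without untreated replicate 2, 3 after quantile normalization and 2 in the ordinary test. The rises numbered 1 without untreated replicate 1, untreated replicate 3, treated replicate 1 or treated replicate 2, and 1 after median centring, without the dimmest probe sets, with an intensity trend, with the block and in the ordinary test.

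Chondroitin sulfate synthesis had 4 rises and 5 falls among 19 genes, and 5 and 5 adjusted over the list alone (camera adjusted p = 0.82). CHST15 and CHST11, a chondroitin 4-O-sulfotransferase that was 3.62-fold higher (adjusted p = 3.04e-07), rose with CHSY1 (0.66) and CSGALNACT2 (0.50). The linkage-region enzymes B3GALT6 (-0.78), B4GALT7 (-0.37), B3GAT3 (-0.27) and XYLT2 (-0.26) fell, as did the sulfotransferase UST (-0.91). Linkage-region enzymes were counted in this list only and not under heparan sulfate synthesis. There were 3 falls without untreated replicate 2 and 3 without treated replicate 1. Heparan sulfate synthesis had 2 rises and 2 falls among 23 genes, and 2 and 1 adjusted over the list alone (camera adjusted p = 0.978). HS6ST2 rose by 1.96 ± 0.11 on the log2 scale (adjusted p = 3.96e-07) from a low level of 2.68, and HS3ST1 was 2.28-fold lower (adjusted p = 1.55e-06). HS3ST3A1 (0.88) rose and HS2ST1 (-0.22) fell, the latter not without untreated replicate 1, untreated replicate 2, treated replicate 2 or treated replicate 3, each of which left 1 fall, as did the intensity trend, the block and the ordinary test. With the dimmest probe sets left out, 0 rises and 1 fall were called.

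Of 23 proteoglycan core genes 4 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.556), against 4 and 4 after quantile normalization and after median centring. Besides VCAN, SRGN, the granule proteoglycan serglycin, was 2-fold higher (adjusted p = 2.11e-06). SDC4 (0.70) and BGN rose, and GPC4 (-0.54) and TGFBR3 (-0.40) fell, with 1 fall left without untreated replicate 2, with the block and in the ordinary test. Lysosomal and other glycosidases had 7 rises and 6 falls among 29 genes, and 7 and 7 adjusted over the list alone (camera adjusted p = 0.747). The falls numbered 10 after quantile normalization and 12 after median centring. Besides HYAL1, NEU1, the lysosomal sialidase, was 1.96-fold higher (adjusted p = 2.19e-06).

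Galectins had 4 rises and 2 falls among 12 genes, also adjusted over the list alone (camera adjusted p = 0.82), with 3 and 4 after quantile normalization and 3 and 3 after median centring. LGALS1 was 3.2-fold higher (adjusted p = 3.96e-07) and LGALS8 2.25-fold lower (adjusted p = 1.11e-05). LGALSL (0.41) and LGALS9 (0.30) rose beside LGALS7, whose probe set may share signal with a near-identical gene copy, and LGALS4 (-0.51) fell. Of 14 siglec genes 3 rose and 1 fell, and adjusted over the list alone 2 rose and 1 fell (camera adjusted p = 0.82). The counts were 1 and 3 after quantile normalization, 2 and 2 after median centring and 1 and 1 without the dimmest probe sets. CD33 was 1.49-fold higher (adjusted p = 0.000168) and SIGLEC6 1.22-fold higher (adjusted p = 0.00713). SIGLEC6 missed the threshold after quantile normalization (0.0778, lowest value 0.00449). SIGLEC14 (0.25) rose and CD22 fell, and no fall was called without untreated replicate 2 (adjusted p = 0.0527 for CD22, lowest value 0.00528).

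Notch pathway genes had 8 rises and 2 falls among 13, also adjusted over the list alone (camera adjusted p = 0.526). MFNG, a fringe glycosyltransferase that modifies Notch, was 2.06-fold higher (adjusted p = 6.34e-06), and the ligand gene DLL3 was 1.89-fold higher (adjusted p = 2.16e-05). The falls were JAG2 (-0.84) and LFNG (-0.38). The rises numbered 5 without untreated replicate 1, 5 without treated replicate 1, 5 after median centring, 5 with the block and 4 in the ordinary test. Of 34 chemokine and interferon genes 7 rose and 2 fell, also adjusted over the list alone (camera adjusted p = 0.576), against 5 and 5 after quantile normalization and 6 and 5 after median centring. CCL5 rose by 2.05 ± 0.12 on the log2 scale (adjusted p = 5.17e-07), and CXCL11, an interferon-inducible chemokine, was 2.97-fold higher (adjusted p = 1.17e-06). CXCL5 (-0.34) and CX3CL1 (-0.30) fell, with 0 falls in the ordinary test, 1 without untreated replicate 2 and 1 without treated replicate 1. The interferon genes measured, IFNB1 (-0.003) and IFNG (-0.01), were not called.

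Fibroblast growth factors and their receptors had 5 rises and 2 falls among 26 genes, also adjusted over the list alone (camera adjusted p = 0.629). FGF19 was 2.03-fold higher (adjusted p = 1.21e-06) and FGF11 1.95-fold higher (adjusted p = 1.22e-05). FGF13 (1.11), FGFR3 (0.98) and FGFR1 (0.37) rose and FGFR2 (-0.54) and FGF18 (-0.27) fell, with 1 fall left without untreated replicate 2 and 1 without treated replicate 1. From a list of 10 glycan genes reported elsewhere as silenced by epigenetic marks, drawn up from general knowledge, 9 were measured. In limma's test 2 rose, ST3GAL6 and B4GALT1, and 0 fell, also adjusted over the list alone (camera adjusted p = 0.82). At an unadjusted p under 0.05 there were 2 falls, and 1 in the ordinary test. There were 2 falls after quantile normalization, 2 after median centring and 2 with array weights, with 1 rise in the first of these and 2 in the others. In the ordinary test and without the dimmest probe sets 1 rose. Without untreated replicate 2 there was 1 rise, and without untreated replicate 3 or treated replicate 3 there was 1 fall.

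Among markers of other cell types, 8 of leukocytes were measured. Of these 2 rose, CD33 and KLRD1 (0.25), and CD22 fell (1.19-fold lower, adjusted p = 0.013), also adjusted over the list alone (camera adjusted p = 0.82). There was 1 rise without untreated replicate 1, untreated replicate 2, treated replicate 1 or treated replicate 2, 1 after median centring and 1 in the ordinary test, and no fall without untreated replicate 2. Of 7 stromal and endothelial markers 2 rose and 0 fell in limma's test, also adjusted over the list alone (camera adjusted p = 0.82), with 0 falls at an unadjusted p under 0.05 and 0 in the ordinary test. They were BGN (1.26-fold, adjusted p = 0.011) and PECAM1 (1.23-fold, adjusted p = 0.0403). PECAM1 missed the threshold without untreated replicate 1 (0.119), untreated replicate 2 (0.128), treated replicate 1 (0.116) or treated replicate 3 (0.132), after median centring (0.0917) and in the ordinary test (0.173), in a range from 0.0142. BGN missed it in the ordinary test (0.0704, lowest value 0.00725), which left 0 rises, and 1 fall was called after median centring.

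**Figure D3:**
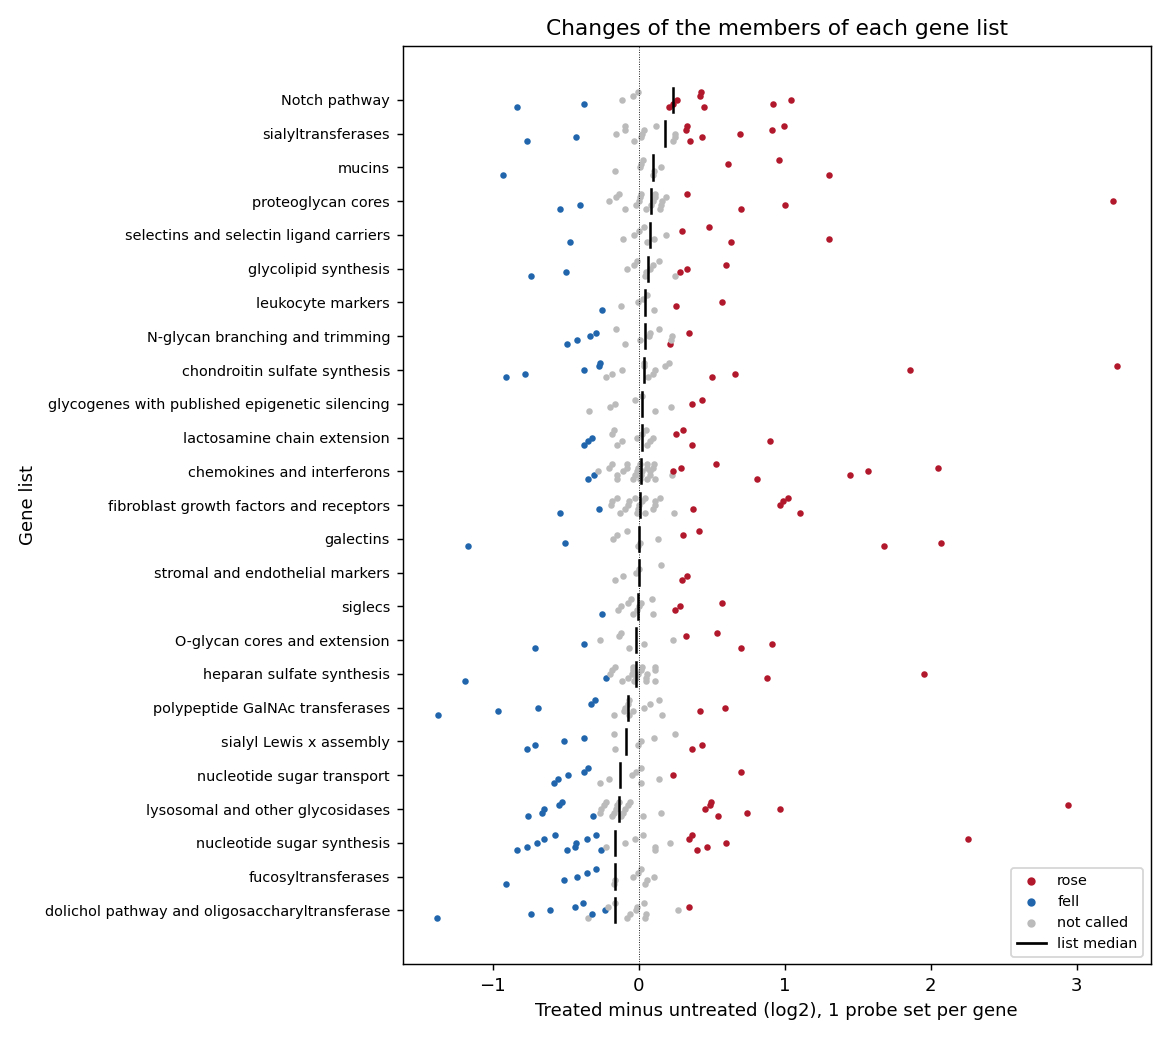
Each point is 1 measured gene of a list, placed at its treated minus untreated difference (log2), with rises in red, falls in blue and genes not called in grey, and a black line at the list median. Lists are ordered by median, from -0.16 for the dolichol pathway, fucosyltransferases and nucleotide sugar synthesis to 0.24 for the Notch pathway, and most lists hold both rises and falls.

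Of the 25 lists, 0 passed an adjusted p under 0.05 in limma's camera test, 1 passed unadjusted (the dolichol list), and the smallest adjusted p was 0.374. With an estimated correlation 0 passed, unadjusted or adjusted, with a smallest adjusted p of 0.89. The fry test called 12 lists for a shift on balance in one direction and all 25 for changes in either direction. It does not compare a list with other genes. With 34.8% of all probe sets called, most lists were likely to pass for changes in either direction, so that result sets no list apart. In 7 lists the median, the mean and the test do not all share a sign. They are those of O-glycan cores, lactosamine chains, N-glycan branching, heparan sulfate, siglecs, glycosidases and stromal markers. For stromal markers this is only because the median is 0, with a mean of 0.071 and a test direction upward.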

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

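All settings here were chosen before the data were examined. The number of called probe sets was 438 and ranged from 330 (adjusted p under 0.01) to 508 (median centring), always within 1.5 times. It was 360 without the dimmest probe sets, 459 with an intensity trend, 495 with array weights, 485 after quantile normalization, 344 in the ordinary test, 503 at an adjusted p under 0.1 and 376 to 440 with 1 array left out. Of the 438, 401 were also called after quantile normalization and 408 after median centring. With the replicate number as a block 394 were called, 392 of them among the 438. The block is an alternative only, because arrays of the same number did not deviate together. The correlations of their deviations were -0.27, 0.04 and -0.11. No untreated array correlated best with the treated array of its own number.

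Over the 67 named genes, 831 of the values under alternatives kept direction and side of the threshold, 14 missed a threshold passed in the main test, 7 newly passed it and 7 turned direction. The turned values belong to FUT9 and FUT5, which were not called in any setting: FUT9 (0.02) was at -0.052 after median centring, -0.034 with array weights, and -0.056 to 0.086 with 1 array left out, and FUT5 (-0.01) at 0.023 with array weights and -0.049 to 0.045 with 1 array left out. For the dimmest genes, such as ST3GAL6 and FUT9, the filter leaves no value.

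The unadjusted camera p of the sialyl Lewis x list lay between 0.226 and 0.392 in the other settings, while fry, which asks a different question, gave unadjusted p of 0.00528 and 0.00102. In the other lists 12 values turned direction, all with no call. After quantile normalization these were siglecs (unadjusted camera p of 0.652; the values below are of the same kind or, where named, unadjusted fry p) and silenced glycan genes (0.965). Lactosamine chain extension turned without the dimmest probe sets (0.708), with an intensity trend (0.995), with array weights (0.94), in fry (0.251), and without untreated replicate 2 or treated replicate 3, in a range of 0.869 to 0.961 with 1 array left out. Heparan sulfate synthesis turned in fry (0.579) and without untreated replicate 1 or treated replicate 2, in a range of 0.721 to 0.996 with 1 array left out, and glycosidases turned in fry (0.263). The cause was not tested. The filter on dim probe sets left 2 of 7 rises among sialyltransferases and 2 of 7 among chemokines, since fewer genes were tested. Without scanner values, signal over background is unknown, and changes of the dimmest probe sets are the least certain.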

Other observations

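The gene families described here were chosen after the values were seen, as were all the tests below except those of other splits of the arrays, of an admixture in untreated replicate 3 and of a level-dependent bias of that array. Genes named as hyaluronan synthases (HAS) or as hyaluronidase family members (HYAL) had 4 rises and 1 fall among 7 measured, and 4 and 2 after median centring. They were grouped by symbol, and not every member need act on hyaluronan. Besides HYAL1, the hyaluronan synthase HAS3 was 3.54-fold higher (log2 change 1.82 ± 0.12 SE), HYAL4 2.68-fold and HAS1 1.54-fold higher, and HYAL3 was 1.28-fold lower. Fisher's exact test, two-sided, against the other genes gave p = 0.0313 for the rises, which did not pass over the 34 tests of 17 families (adjusted p = 0.355). Within the Wnt receptors, FZD5 was 2-fold higher while FZD7 was 2.28-fold and FZD2 2.81-fold lower, and 3 of 10 rose and 3 fell (2 and 2 after quantile normalization, 1 and 3 after median centring). Of 18 WNT ligand genes 6 rose and 1 fell (5 and 3 after either rescaling), led by WNT6 (2.16-fold higher). Of 6 cytosolic sulfotransferases 1 rose and 3 fell in all 3 scalings, and the 1C group went apart, with SULT1C4 4.07-fold higher and SULT1C2 3.63-fold and SULT1C3 2.04-fold lower.

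Growth factor ligands also went both ways. PDGFA was 3.37-fold higher, and ANGPT1 (1.78-fold), ANGPT2 (1.67-fold) and PDGFD (1.6-fold) rose, while VEGFA (1.89-fold), VEGFB (1.69-fold) and PDGFC (1.67-fold) were lower, in all 3 scalings with 4 rises and 3 falls among 12 genes. Of 22 BMP, GDF, activin and TGF-beta ligand genes 6 rose and 2 fell (6 and 4 after either rescaling), with INHBB, an inhibin subunit, 2.54-fold and GDF15 1.97-fold higher beside BMP7, against the fall of TGFB3. Of 16 chemokine receptor genes CXCR4 alone rose (2.82-fold, adjusted p = 2.01e-07), and 0 fell in limma's test, with 0 falls at an unadjusted p under 0.05, 0 in the ordinary test and 1 after either rescaling. None of the families in these paragraphs passed adjustment over the 34 tests, and they were not tested without untreated replicate 3.

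Across the 10 splits of the 6 arrays into 3 and 3, the treated against untreated split called 438 probe sets and the highest of the others called 0 in limma's test. At an unadjusted p under 0.05 the counts were 528 and at most 55. As large a result came from 1 of the 10 splits, the real one, and 10 splits are too few for a share under 0.05. The other splits mix treated and untreated arrays, so the difference between the groups widens their spread and lowers their counts. Their counts are therefore no measure of calls by chance.

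Untreated replicate 3, whose title conflicts with its other labels, lay part of the way toward the treated arrays: its position was 0.079 ± 0.011 (bootstrap SE over probe sets) on a scale from the untreated (0) to the treated (1) arrays, with the other untreated arrays at -0.044 and -0.041, values that largely follow from the first, since positions within a group add to about 0. A treated array under a wrong label would lie above 0.5, which this value argues against. If values were proportional to RNA amount, an admixture of treated RNA would give the same mixing share in rises and falls. The fit gave 2.51% ± 0.887 over 47 rises and 20.1% ± 3.68 over 20 falls, a difference of 17.6 points (SE 3.79). RMA compresses differences between dim probe sets, and 2-fold rises lay mostly at low levels, so unequal shares cannot decide on an admixture. The sets were also chosen with the same untreated arrays that served as the baseline of the fit. A bias of the array that depends on level may account for part of the shift toward the treated arrays. Removing a smooth trend brought the position to 0.048 ± 0.011, under the bound of 0.05 set beforehand but by less than its standard error. This bias stays open under a margin of 2 standard errors that was added after the value was seen. The errors here are over probe sets of this array and not between arrays, so whether it stands apart from ordinary variation between arrays was not tested, and that and a difference between cultures also stay open.

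Probe sets of RPL28, RPL32, RPL34, RPL37 and EEF1A1, genes of the translation machinery, changed by a median of -1.25 on the log2 scale, while ribosomal protein genes as a family had 9 falls among 41 (17 after median centring, 8 after quantile normalization), with no excess over other genes detected (Fisher's exact test, two-sided, p = 0.408, adjusted p = 0.6). With 1 probe set per gene, the brightest, they had 0 rises in limma's test, 0 at an unadjusted p under 0.05 and 0 in the ordinary test, the only 1 of the 34 tests to pass (Fisher's exact test, two-sided, p = 0.000168, adjusted p = 0.00572), but most of their probe sets lie near the top of the range, where a rise is hard to see, so this count decides nothing. After a smooth trend of the change on the level was removed, the median of RPL28, RPL32, RPL34, RPL37 and EEF1A1 was -1.19. The median standard error was 0.097. These genes were picked after their falls were seen, so a smooth trend could hardly have removed the change. The test therefore cannot decide on a level-dependent bias between the groups. A general loss of ribosomal protein mRNAs, hidden where probe sets are near the top of the range, may contribute. Of the 6 ribosomal protein probe sets with a level under 10, 4 fell, but 3 of those 4 are from the genes named above. Of the others RPL21 fell and RPL27A was not called. A dimmer probe set of RPL31 rose by 0.78, while the brightest of that gene was not called. Which of a general loss and a change in what these few probe sets bind applies cannot be told apart here, because so few lie at low levels, and an effect of the drug on these genes also stays open.

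Rises of 2-fold or more (42) outnumbered falls (16). A constant shift of each array is argued against as the whole cause. After each array was centred on its median, 35 rises and 19 falls, or 1.84 rises per fall, were left. Centring cannot test a difference in spread between arrays, which also stays open. Lower quartiles were 4.25 to 4.3 in untreated and 4.39 to 4.42 in treated arrays. Upper quartiles were 8 to 8.14 in untreated and 8 to 8.07 in treated arrays. For the rest, 2 further explanations that are not exclusive stay open. A floor under dim probe sets would hide falls. Above the median untreated level 48.1% of 2-fold changes were rises (13 against 14, exact 95% interval 28.7% to 68.1%). At or below it there were 29 rises and 2 falls. The untreated level is 1 end of the change, so this split by itself sorts rises downward and falls upward. Levels were then taken from untreated replicate 1 and changes from the other 5 arrays. That removes noise shared by level and change, but not the sorting itself. Untreated replicate 1 correlated with the other untreated arrays at 0.9982 and 0.9978, so its level is still 1 end of the change. This gave 16 rises and 13 falls above the median, and 31 and 2 at or below it. Falls stayed few at low levels, but these counts cannot show that a floor is the reason. As a hypothesis, genes with a low level before treatment may also rise more often, though DNA methylation itself was not measured here. On the split by untreated replicate 1, 4.92% of 630 probe sets at or under the median rose 2-fold against 2.54% of 629 above it (Fisher's exact test, two-sided, p = 0.0363). The upper part holds probe sets near the top of the range, where a rise is hard to see. Part of this difference may come from those probe sets, and part from the sorting of rises downward. The test therefore cannot decide on the hypothesis.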
